A study of Mus musculus with 23 samples.

How the data were processed

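The data were gene counts from polyadenylated RNA of the mouse hippocampus on postnatal day 14, in 23 libraries of 6 groups (3 anemia levels in 2 sexes). Per the labels' protocols, RNA was isolated with the Invitrogen RNAqueous kit and libraries were made by Illumina TruSeq protocols. The deposited table holds whole-number read counts per gene that the authors had not normalized, as its values show. Per the submitters' processing notes, FastQC, TopHat2 version 2.0.13, Subread and edgeR were used with the mouse genome build mm10. The role and order of these tools, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Where a gene has a near-identical copy or an antisense partner, its counts were therefore treated as uncertain.

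The table has 24421 rows, and all its columns were matched to samples by name, with 0 left over. Of the rows, 23350 (95.6%) carry a gene symbol of GENCODE release M21, which gave the positions (mm10, also called GRCm38), GC content and transcript length. Positions are those of whole genes, since counts per gene do not tell exon from untranslated region. A further 27 rows are named by a date, as spreadsheet software renders some gene symbols, with 2 such names on 2 rows each. They held 0.328% to 0.35% of the counts of a library, were kept in library sizes and tests and are not named. Rows of haemoglobin genes are listed at 0 or close to it, so haemoglobin was not tested. The mitochondrially encoded genes of the fixed lists are not among the rows used here, and in all 27 genes of the fixed lists had no row.

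Counts were compared between replicates before they were averaged. All pairs within a group differed by more than sampling noise (chi-square per degree of freedom 3 to 30.1), so no library was counted as a copy of another. Groups were taken from the labels alone.

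The main test was edgeR's quasi-likelihood test with robust fitting on the counts as deposited. All 23 libraries entered a single fit with 6 group means and TMM normalization, so that all comparisons shared the same estimate of the spread. Genes passed a low-count filter (edgeR's filterByExpr, minimum count 10, minimum total 15), which left 15475. P-values were adjusted by the Benjamini-Hochberg method at 0.05 within each comparison. Levels are given as CPM, and log2 CPM used a prior count of 2. Standard errors are of the log2 change on edgeR's scale. The comparisons were mPIA and sPIA with NBC and sPIA with mPIA within each sex, the difference between the sexes in each anemia effect, and females with males in NBC.

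Gene lists were written before the data were examined: 39 lists of pathways and cell types, of which 38 could be tested. Each was tested with camera (limma) on voom log2 CPM at a preset correlation of 0.01, again with an estimated correlation, and with the rotation test fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Members that passed were counted over all genes tested and adjusted over the list alone. Genes to be named were also chosen by a rule fixed in advance. For each comparison of anemia with NBC the rule took the called genes with an average log2 CPM of at least 1, without predicted gene models and named pseudogenes, and among them the 6 largest rises and the 6 largest falls. It added up to 4 called members of each list by smallest p, all called genes where fewer than 12 passed, and Tfrc, Vegfa, Slc2a1, Bdnf and the haemoglobin gene Hbb-bs in every case. For other comparisons it took the 5 largest changes in each direction. Genes named outside the rule, after their values had been seen, were Ttr, Ankrd37, Kdr and Cxcl12 in mPIA females, Fbxo44, and Adm, Kdr, Cxcl12, Nr4a1, Egr4 and Arc in comparisons where the rule did not take them. They also include the genes shared between comparisons and those compared between sPIA females and NBC males. The sex difference of the sPIA effect was also looked up for all genes that the rule took in a comparison with NBC, and those that passed, such as Sst, Fezf2 and Sox9, are named for it outside the rule. Not all genes that the rule took are reported here.

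Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. The test was checked on simulated counts drawn from the means and library sizes of the real libraries, with 100 genes changed 1.5-fold and 100 changed 2-fold. For mPIA against NBC in females it recovered 64% of the 1.5-fold and 80% of the 2-fold changes over 15314 genes, with 8.28% false calls. Against NBC these were 70%, 73% and 4.03% in mPIA males (15318 genes). They were 60%, 77% and 4.86% in sPIA females (15308) and 60%, 73% and 4.32% in sPIA males (15326). In the design of mPIA against NBC in females camera called a simulated list of 30 genes raised 1.2-fold (adjusted p = 1.77e-29) and 0 of 37 unchanged lists. Counts drawn from means and library sizes hold no correlation between genes, so false list calls from correlation were not tested.

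Alternatives were RLE and upper quartile normalization, no low-count filter, a filter at a CPM of 1 in 4 samples, DESeq2, limma-voom without and with sample quality weights, and a fit of only the groups compared. Others were the replicate number or the library code prefix as a block, haemoglobin and mitochondrial genes left out, and each mouse left out in turn. After the data had been seen, 2 alternatives were added: the mean log2 CPM of 14 choroid plexus genes as a covariate, and the removal of a spline of each library on GC content and log2 transcript length, followed by limma. The comparisons of females with males within mPIA and within sPIA were also added then. A further NBC male named by the design text was not analysed here, and sequencing reads were not used.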

Results

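Polyadenylated RNA was sequenced from the hippocampus of mouse pups on postnatal day 14. The pups belonged to 3 levels of anemia caused by repeated blood draws (phlebotomy-induced anemia, PIA), a model of the blood loss of preterm infants through sampling. Non-bled controls (NBC) received only a needle prick. Pups with moderate anemia (mPIA) were bled toward a haematocrit, the share of blood volume taken up by red cells, of 25%, and pups with severe anemia (sPIA) toward 18%. Bleeding began on postnatal day 3 with draws of 5.25 µl per g of body weight, 2 times a day, followed by 3.5 µl per g daily once the goal had been reached. Both sexes were studied, which gave 6 groups: 4 libraries in each, except NBC males with 3 (numbered 2, 3 and 4). The design text describes 4 animals of each sex and level, so each library was read as a separate mouse.

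Library totals, in mega-counts (M), lay between 15.2 and 26.4 M, apart from mPIA female 3 with 44.4 M. Mean totals were 17.1 ± 1.5 M (SD, n = 4) in NBC females, 24.5 ± 13.3 M (SD, n = 4) in mPIA females and 19.8 ± 1.63 M (SD, n = 4) in sPIA females. In males the means were 22 ± 3.83 M (SD, n = 3) in NBC, 21.9 ± 1.95 M (SD, n = 4) in mPIA and 20.1 ± 1.38 M (SD, n = 4) in sPIA. The spread between mice within a group, as the biological coefficient of variation, was 8.66% in NBC females, 6.85% in mPIA females and 13.3% in sPIA females. It was 20.7% in NBC males, 11% in mPIA males and 15.2% in sPIA males. Sex-specific transcripts matched the recorded sex in all 23 libraries. Xist, the RNA that coats the inactive X chromosome, lay at 900 to 1510 counts per mega-count of the library (CPM) in females and at no more than 0.837 CPM in males. Ddx3y, a Y-linked gene, lay at 75.2 to 92.7 CPM in males and at no more than 0.118 CPM in females.

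The first principal component of the libraries held 18.2% of the variance and the second 13%. NBC male 4 stood apart at 66.5 on the first component and 40.2 on the second, while the other libraries lay between -19.4 and 29.5 on the first. Ttr, the transthyretin gene and an abundant transcript of the choroid plexus, differed by orders of magnitude between mice of the same group. It was chosen for display after its values had been seen. Ttr lay at 1.23, 2460 and 4380 CPM in NBC males 2, 3 and 4, at 1.37 to 29.4 CPM in mPIA males and at 6.16 to 135 CPM in sPIA males. In females it lay at 21.7 to 2020 CPM in NBC, 12 to 231 CPM in mPIA and 2.29 to 1320 CPM in sPIA.

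**Figure D1:**
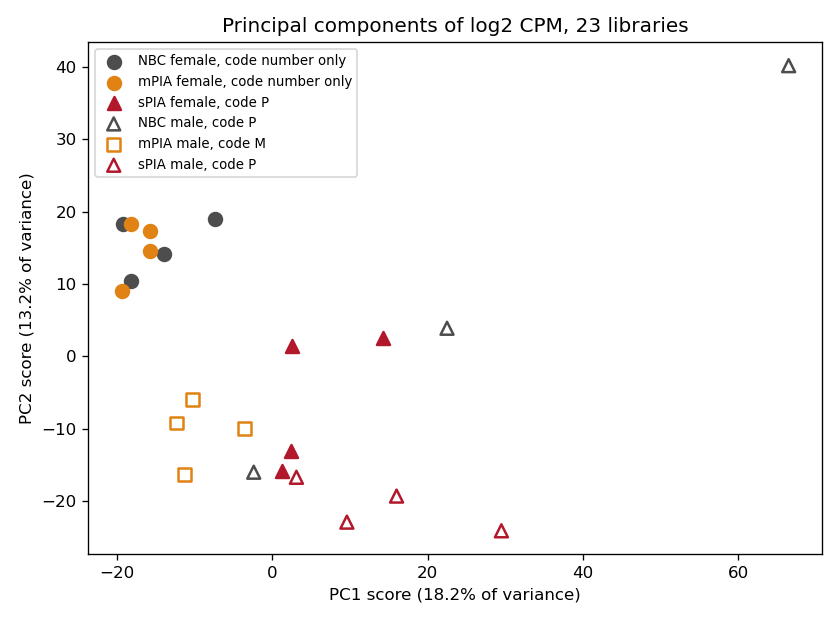
First (horizontal, 18.2% of variance) and second (vertical, 13%) principal component of log2 CPM, 1 marker per library, with NBC in grey, mPIA in orange and sPIA in red, filled markers for females, open markers for males, and the marker shape giving the library code series (circles numbers alone, squares M, triangles P). NBC male 4 lies apart at 66.5 and 40.2.

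The library codes in the labels followed the groups, and their meaning is not given in the sources used here. Codes that began with a number (86, 90 or 91) belonged to the NBC and mPIA females, codes that began with M to the mPIA males, and codes that began with P to the sPIA females, NBC males and sPIA males. The S numbers in the codes were 13 to 20 in sPIA, 38 to 40 in NBC males, 41 to 44 in mPIA males and 48 to 55 in NBC and mPIA females, where the groups interleaved. Of the comparisons with controls, only that of moderate anemia in females was therefore separate from the codes. Severe anemia in males had controls of the same P series but was split from them by S number, and for the other comparisons, those of severe with moderate anemia included, the code series and the group could not be told apart. The relation of a gene's level to its GC content also differed between these groups. Spearman's rho across genes, which are not independent replicates, between GC content and a library's deviation from the mean over libraries was 0.19 to 0.57 in the NBC females and 0.17 to 0.49 in the mPIA females. It was -0.45 to 0.03 in the sPIA females, -0.27 to 0.01 in the NBC males, -0.1 to 0.3 in the mPIA males and -0.42 to -0.08 in the sPIA males.

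**Figure D2:**
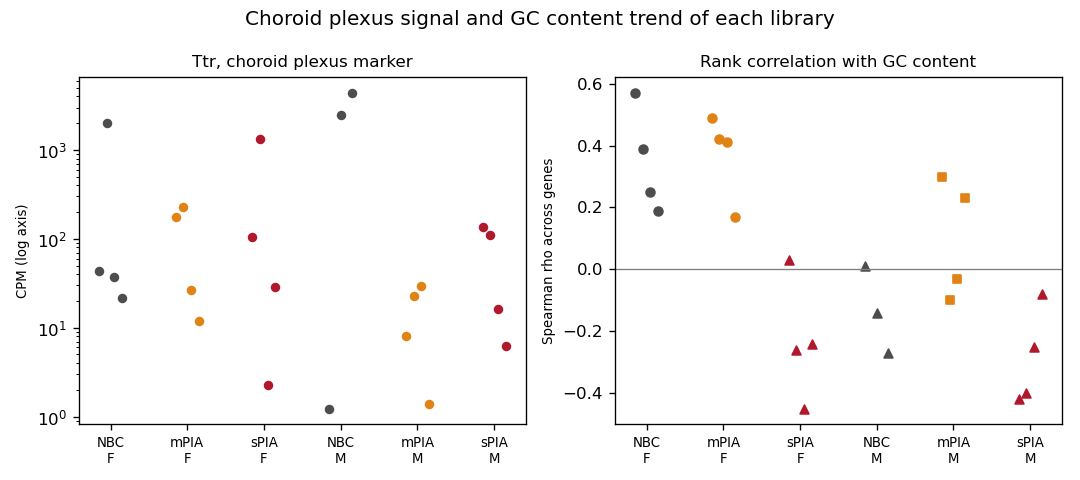
Left, Ttr level (CPM, log axis) in each library by group. Right, Spearman's rho across genes of each library's deviation with GC content, with a grey line at 0. Markers are filled for both sexes, and shapes in the right panel give the code series (circles numbers alone, squares M, triangles P). Ttr spans 1.23 to 4380 CPM in NBC males, and rho is 0.19 to 0.57 in NBC females against -0.45 to 0.03 in sPIA females.

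Moderate anemia was first compared with no bleeding in females. Adm, which encodes the vasodilator peptide adrenomedullin and is induced by hypoxia (chromosome 7, 110627661 to 110629820, plus strand), rose from 1.38 ± 0.23 CPM (SD, n = 4) to 3.63 ± 0.748 CPM (SD, n = 4). The log2 change was 1.40 (SE 0.24, adjusted p = 0.0365, edgeR quasi-likelihood test), and all 4 mPIA libraries lay above all NBC libraries. Adm was the only gene that passed among 15475 tested. Vegfa, the main growth factor for blood vessels, had a log2 change of 0.35 (SE 0.09), from 89.5 ± 6.99 to 114 ± 5.67 CPM (SD, n = 4 each), and did not pass over all genes (adjusted p = 1). The log2 changes of the glucose transporter Slc2a1, the transferrin receptor Tfrc and the neurotrophin Bdnf were 0.33 (SE 0.12), 0.39 (SE 0.25) and -0.10 (SE 0.11), each with adjusted p = 1.

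As a group, hypoxia and HIF targets were higher than other genes in mPIA females. Of 33 measured members 25 had a positive change, 1 rose over all genes and 3 rose when adjusted over the list alone, namely Adm, Vegfa (adjusted p = 0.00719) and Ankrd37 (log2 change 0.71, SE 0.19, adjusted p = 0.00857). The list passed the camera test (adjusted p = 1.23e-13, and adjusted p = 8.01e-05 with an estimated correlation). Endothelial markers were higher in 20 of 24 members with none past the threshold singly, and the list passed (adjusted p = 1.27e-15, and adjusted p = 0.0194 with an estimated correlation). Glucocorticoid response genes were higher in 21 of 23 members (adjusted p = 1.63e-07, and adjusted p = 0.0489 with an estimated correlation), with none past the threshold singly. The rotation test fry, which asks whether a list's own genes move in one direction, passed for the hypoxia list alone (adjusted p = 0.0181). Angiogenesis signalling was higher in 16 of 25 members, of which 2 rose when adjusted over the list alone (camera adjusted p = 7.89e-06, and adjusted p = 0.295 with an estimated correlation). These were Kdr, the main VEGF receptor (log2 change 0.27, SE 0.08, adjusted p = 0.0355 over the list), and Vegfa. Ankrd37 and Kdr were named after their values had been seen.

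A further 8 lists passed camera in mPIA females but not with an estimated correlation, where adjusted p was 0.326 to 0.747. Markers of pericytes and smooth muscle were higher in 18 of 19 members (adjusted p = 7.89e-06), myelin genes in 25 of 26 (adjusted p = 0.00172), complement genes in 12 of 16 (adjusted p = 0.00616), immediate early genes in 22 of 28 (adjusted p = 0.00616) and cytokine and NF-kB genes in 19 of 28 (adjusted p = 0.0427). Choroid plexus and ependymal markers were lower in 20 of 21 members (median -1.35, adjusted p = 0.00698), beside Ttr at 2020 CPM in NBC female 2. Synapse and postsynaptic density genes were lower in 27 of 31 (adjusted p = 0.00328) and dendrite and axon growth genes in 28 of 31 (adjusted p = 0.00698), with medians of -0.03 and -0.05. No member of these 8 lists passed over all genes, and within the cytokine list Cxcl12 passed when adjusted over the list alone (log2 change 0.44, SE 0.12, adjusted p = 0.0416). Each of these calls depended on single libraries. Without NBC female 2 the choroid plexus and ependyma median was 0.11 (adjusted p = 0.832), and its call was also lost without mPIA female 3 (0.0834) or mPIA female 4 (0.117). Without mPIA female 3 the call was lost for pericytes and smooth muscle (0.193), complement (0.193), myelin and mature oligodendrocytes (0.196), synapse and postsynaptic density (0.15), cytokines (0.273) and immediate early genes, whose median turned to -0.02 (0.818). Other losses were complement without NBC female 4 (0.222) or mPIA female 1 (0.0654), immediate early genes without NBC female 4 (0.198), and myelin and mature oligodendrocytes without NBC female 2 (0.0833), NBC female 4 (0.139), mPIA female 1 (0.13) or mPIA female 2 (0.646). Cytokines were lost without NBC female 1 (0.0699), NBC female 3 (0.144), NBC female 4 (0.139) or mPIA female 1 (0.147), and synapse and postsynaptic density without NBC female 1 (0.0699) or NBC female 2 (0.413). Dendrite and axon growth was lost without NBC female 1 (0.0784).

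The Adm call in mPIA females itself was lost in 7 of the 8 fits that left out a single mouse. Its adjusted p was 0.111, 0.347, 0.437 and 0.12 without NBC females 1 to 4, and 0.0648, 0.41 and 0.238 without mPIA females 2, 3 and 4. DESeq2 also called this 1 gene, limma-voom called 0 (Adm adjusted p = 0.965), and 55 genes had an unadjusted p under 0.05. Within library code prefixes, fitted as a block, the log2 change of Adm was 1.39 (adjusted p = 0.156) and 0 genes passed.

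Moderate anemia in males was compared with no bleeding in 4 against 3 mice, and 101 of 15475 genes passed, 24 higher and 77 lower. Among the genes that rose, Bhlhe40, a transcriptional repressor of the hypoxia and circadian responses (chromosome 6, 108660629 to 108666925, plus strand), went from 68.3 ± 0.936 CPM (SD, n = 3) to 98.5 ± 3.97 CPM (SD, n = 4), a log2 change of 0.53 (SE 0.09, adjusted p = 0.0111, edgeR). Nr4a1, an activity-induced nuclear receptor, rose from 39.8 ± 14 (SD, n = 3) to 69.9 ± 4.87 CPM (SD, n = 4), a log2 change of 0.81 (SE 0.15, adjusted p = 0.0168). Eng, the endothelial receptor endoglin, rose by 0.46 (SE 0.11, adjusted p = 0.0472). Tsix rose by 1.66 (SE 0.37, adjusted p = 0.0342), but it overlaps Xist on the opposite strand and the strand used in counting is not given in the sources used here, so its value is uncertain. Adm had a log2 change of 0.68 (SE 0.24, adjusted p = 0.15) and Vegfa of 0.28 (SE 0.1, adjusted p = 0.137). Bdnf, Tfrc and Slc2a1 did not pass, with log2 changes of 0.15, 0.33 and 0.08 and adjusted p of 0.551, 0.574 and 0.798.

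The largest falls in mPIA males were those of F5, which encodes coagulation factor V (-3.72, SE 0.82, adjusted p = 0.047), Drc7 and Abca4, a lipid transporter (-2.91, SE 0.62, adjusted p = 0.0377). Drc7, a component of the ciliary dynein regulatory complex (chromosome 8, 95055103 to 95078141, plus strand), fell from 7.1 ± 6.61 CPM (SD, n = 3) to 0.724 ± 0.314 CPM (SD, n = 4), a log2 change of -3.26 (SE 0.55, adjusted p = 0.0143). Dnah11, an axonemal dynein, fell by 2.69 (SE 0.51, adjusted p = 0.0168), Mlf1 by 2.11 (SE 0.43, adjusted p = 0.018) and Foxj1, the master regulator of motile cilia, by 1.16 (SE 0.26, adjusted p = 0.0391). Choroid plexus and ependymal markers were lower in 21 of 21 measured members (median -3.78), of which 1 fell over all genes and 20 when adjusted over the list alone (camera adjusted p = 6.06e-11). Meningeal and fibroblast markers were lower in 20 of 20 (median -1.05, adjusted p = 6.06e-11), with 0 past the threshold over all genes and 12 adjusted over the list alone. Beside these groups, Ttr lay at 2460 and 4380 CPM in NBC males 3 and 4 and at no more than 29.4 CPM in any mPIA male. Blood leukocyte markers were lower in 11 of 12 (adjusted p = 0.00145), where Pf4, a platelet chemokine, fell by 2.19 (SE 0.53, adjusted p = 0.0472). With an estimated correlation each of these 3 lists had adjusted p = 0.37.

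Immediate early genes, the early transcriptional response of neurons to activity, were higher in 25 of 28 members in mPIA males (median 0.32, camera adjusted p = 1.46e-06, and adjusted p = 0.37 with an estimated correlation). Nr4a1 alone rose over all genes, and 11 members rose when adjusted over the list alone. Excitatory neuron markers were higher in 19 of 23 members (adjusted p = 0.019) and synapse and postsynaptic density genes in 24 of 31 (adjusted p = 0.019), with adjusted p = 0.507 for both with an estimated correlation. Lists that were lower were neurogenesis and cell proliferation (24 of 30 members, adjusted p = 0.000339), cholesterol synthesis (18 of 24, adjusted p = 0.00262), where Cyp51 fell by 0.31 (SE 0.07, adjusted p = 0.0419), reactive astrocyte genes (16 of 25, adjusted p = 0.00329), microglia (21 of 25, adjusted p = 0.00736) and iron homeostasis (16 of 25, adjusted p = 0.0412). With an estimated correlation these 5 had adjusted p of 0.37 to 0.529, and the rotation test fry passed for none of the 38 lists. Hypoxia and HIF targets did not pass (adjusted p = 0.186), although Bhlhe40 rose and 5 members rose and 2 fell when adjusted over the list alone. Calls that single libraries ended were iron homeostasis without NBC male 3 (0.0965), NBC male 4 (0.181), mPIA male 2 (0.125) or mPIA male 3 (0.0529), and synapse and postsynaptic density without NBC male 3 (0.0965), NBC male 4 (0.231) or mPIA male 2 (0.168). Excitatory hippocampal neurons were lost without NBC male 3 (0.187), and cholesterol synthesis without NBC male 2 (0.189). Without mPIA male 2 the calls of microglia (0.0532), reactive astrocyte genes (0.0532) and neurogenesis and cell proliferation (0.07) were lost.

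The count for mPIA against NBC in males rested on single mice. It was 1124 without NBC male 2, 32 without NBC male 3, 0 without NBC male 4, and 24, 16, 40 and 7 without mPIA males 1 to 4. It was also 0 with the choroid plexus score as a covariate, an alternative added after the data had been seen, and 0 when only these groups were fitted. DESeq2 called 381 genes, limma-voom 24, and 2475 genes had an unadjusted p under 0.05. Without NBC male 4, Bhlhe40, Nr4a1 and Drc7 had log2 changes of 0.51, 0.60 and -2.22, each with adjusted p = 0.129, so Bhlhe40 lost its call at nearly the same change. Nr4a1 was also lost without NBC male 3 (0.0676), mPIA male 2 (0.0539) or mPIA male 4 (0.0518) and Drc7 without mPIA male 4 (0.0518). Without NBC male 4 the log2 changes of Dnah11, Mlf1 and Foxj1 were -1.57, -1.54 and -0.82, with adjusted p of 0.238, 0.238 and 0.303. These 3 genes, F5, Abca4, Pf4, Cyp51, Eng and Tsix lost their calls in 4 to 6 of the 7 fits that left out a mouse.

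Between sPIA and NBC females 2472 of 15475 genes passed (16%), 1256 higher and 1216 lower, the largest count of the comparisons with controls. Among the genes that rose were some of oxygen response and vessel growth. Adm rose from 1.38 ± 0.23 to 4.71 ± 1.44 CPM (SD, n = 4 each), a log2 change of 1.77 (SE 0.24, adjusted p = 3.5e-05, edgeR), and Vegfa (chromosome 17, 46016993 to 46032369, minus strand) from 89.5 ± 6.99 to 127 ± 17.8 CPM (SD, n = 4 each), a log2 change of 0.50 (SE 0.09, adjusted p = 0.000439). Kdr (chromosome 5, 75932827 to 75978458, minus strand) rose from 42.9 ± 2.77 to 63.7 ± 6.98 CPM (SD, n = 4 each), a log2 change of 0.57 (SE 0.08, adjusted p = 5.43e-05). Cxcl12, a chemokine of vessel and neuron development (chromosome 6, 117168535 to 117181367, plus strand), rose from 67.1 ± 4.89 to 113 ± 14 CPM (SD, n = 4 each), a log2 change of 0.74 (SE 0.12, adjusted p = 0.000309). These 4 genes passed in every fit that left out a mouse and after removal of each library's GC and length trend.

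**Figure D3:**
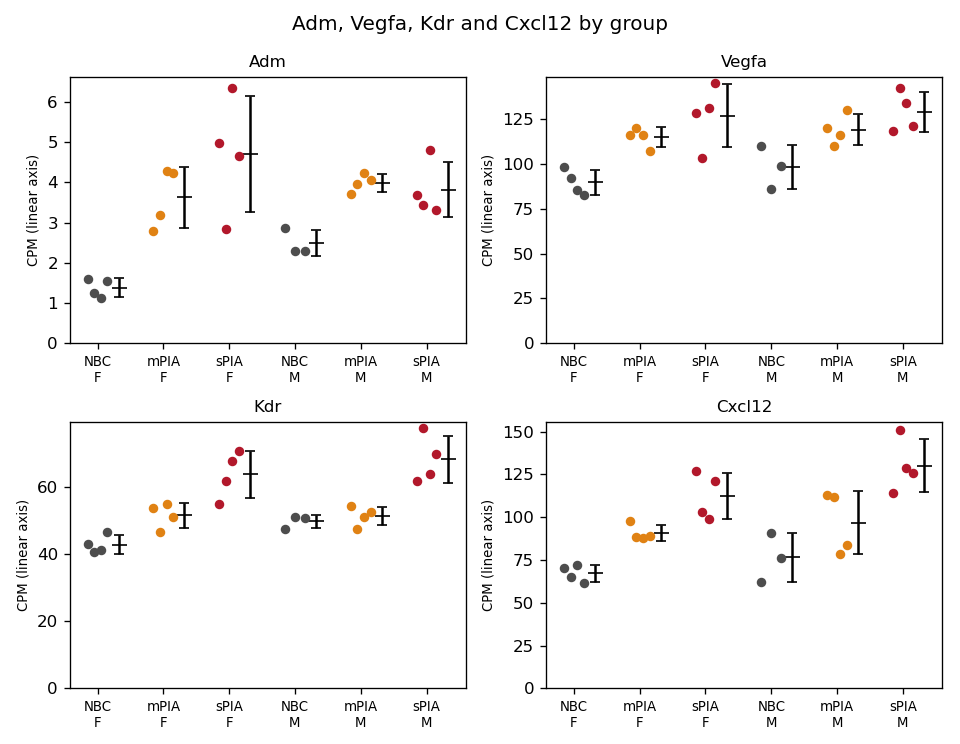
CPM of Adm, Vegfa, Kdr and Cxcl12 in each library by group on linear axes, with filled markers for both sexes and bars for the group mean ± SD. Kdr averages 42.9 CPM in NBC females, 63.7 CPM in sPIA females, 49.8 CPM in NBC males and 68.2 CPM in sPIA males.

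Hypoxia and HIF targets were higher in 25 of 33 members in sPIA females, with 7 risen and 2 fallen over all genes and 8 risen and 2 fallen when adjusted over the list alone. Besides Adm and Vegfa, Nrn1, a neuritin that promotes neurite growth, rose by 0.46 (SE 0.07, adjusted p = 5.7e-05) and P4ha1, a collagen prolyl hydroxylase, by 0.33 (SE 0.07, adjusted p = 0.003). The list passed camera (adjusted p = 0.0103, and adjusted p = 0.313 with an estimated correlation) and the rotation test fry (adjusted p = 0.000991). Angiogenesis signalling was higher in 19 of 25 members, with 7 risen and 1 fallen, and 10 risen and 1 fallen when adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.678 with an estimated correlation). Flt1, a VEGF receptor, rose by 0.57 (SE 0.13, adjusted p = 0.00327) and Adgrl4, an endothelial adhesion receptor, by 0.61 (SE 0.13, adjusted p = 0.00269). Of 24 endothelial markers 5 rose and 1 fell, but the list did not pass (adjusted p = 0.0954). Eng rose by 0.45 (SE 0.1, adjusted p = 0.00417), whereas Mfsd2a, the lipid transporter of the blood-brain barrier, fell by 0.49 (SE 0.11, adjusted p = 0.0027). P4ha1 lost its call after removal of the GC and length trend (0.24, adjusted p = 0.0632).

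Some transcripts of inhibitory interneurons were lower in sPIA females. Sst, the somatostatin gene (chromosome 16, 23889573 to 23890958, minus strand), fell from 175 ± 12.5 to 74.8 ± 13.9 CPM (SD, n = 4 each), a log2 change of -1.22 (SE 0.13, adjusted p = 1.53e-05). Npy, which encodes neuropeptide Y, fell by 0.73 (SE 0.14, adjusted p = 0.00101), Lamp5 by 0.62 (SE 0.12, adjusted p = 0.000885) and Slc32a1, the vesicular GABA transporter, by 0.46 (SE 0.08, adjusted p = 0.000342). Inhibitory interneurons as a list were lower in 18 of 24 members, with 5 fallen and 1 risen over all genes and 5 fallen and 2 risen when adjusted over the list alone. The list passed camera (adjusted p = 0.0124, but adjusted p = 0.678 with an estimated correlation) and fry (adjusted p = 0.0164), and lost its camera call without sPIA female 1 (0.0619). Sst, Npy and Lamp5 passed in every fit that left out a mouse and after removal of the GC and length trend, and Slc32a1 lost its call with that removal (-0.23, adjusted p = 0.0637).

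The largest falls in sPIA females were those of Nxph3, Rxfp1 (-2.93, SE 0.81, adjusted p = 0.0207) and Nts, and Fezf2 also fell. Fezf2, a transcription factor of subcortical projection neurons (chromosome 14, 12342094 to 12348189, minus strand), fell from 49.7 ± 4.11 to 24.4 ± 3.38 CPM (SD, n = 4 each), a log2 change of -1.03 (SE 0.14, adjusted p = 3.94e-05). Nxph3, a secreted synaptic protein (chromosome 11, 95509845 to 95514570, minus strand), fell from 24 ± 10.3 to 2.94 ± 1.41 CPM (SD, n = 4 each), a log2 change of -3.04 (SE 0.60, adjusted p = 0.00255). Nts, the neurotensin gene, fell from 20.8 ± 7.85 to 2.79 ± 1.68 CPM (SD, n = 4 each), a log2 change of -2.89 (SE 0.59, adjusted p = 0.00337). Cplx3, a complexin, fell by 2.23 (SE 0.48, adjusted p = 0.00389). Rxfp1 lost its call without NBC female 1 (0.0645) or sPIA female 3 (0.0711). Fezf2, Nxph3, Nts and Cplx3 passed in every fit that left out a mouse and after removal of the GC and length trend. Yet Nxph3, Nts and Cplx3 were also low in NBC female 2 (9.71, 9.38 and 2.86 CPM) and NBC male 2 (4.79, 3.6 and 2.22 CPM). The share of bordering tissue was not tested as a source. Of the 21 measured markers of neocortex and striatum, the tissues that border the hippocampus, 5 fell and 1 rose, both over all genes and adjusted over the list alone. The list did not pass camera (adjusted p = 0.131) but passed the rotation test fry (adjusted p = 0.0486).

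**Figure D4:**
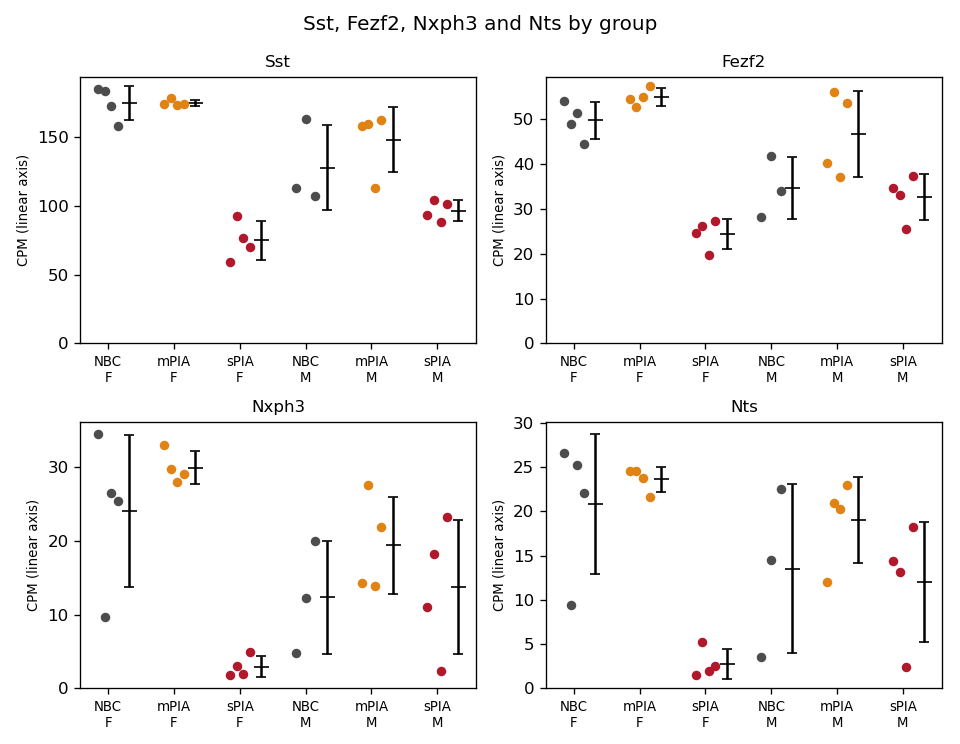
CPM of Sst, Fezf2, Nxph3 and Nts in each library by group on linear axes, with filled markers for both sexes and bars for the group mean ± SD. In sPIA females Sst averages 74.8 CPM against 175 CPM in NBC females, and Nxph3 2.94 against 24 CPM.

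Of 39 nuclear genes of oxidative phosphorylation 33 were lower in sPIA females, by small amounts, and 10 fell over all genes and 17 when adjusted over the list alone, with none risen. Ndufa4 fell by 0.31 (SE 0.06, adjusted p = 0.000716) and Cox5b, a subunit of cytochrome c oxidase, by 0.37 (SE 0.07, adjusted p = 8e-04). The list passed camera (median -0.16, adjusted p = 2.25e-06, but adjusted p = 0.678 with an estimated correlation) and fry (adjusted p = 0.0437). Cytosolic ribosomal proteins were lower in 26 of 38 members, with 11 fallen and 1 risen, and 12 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.894 with an estimated correlation). Rpl19 fell by 0.61 (SE 0.14, adjusted p = 0.00468), although ribosomal protein genes share reads with processed copies and are uncertain for that reason. After removal of the GC and length trend the cytosolic ribosomal proteins list had a median of -0.01 (adjusted p = 0.942).

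Genes of neuronal growth and signalling moved in both directions in sPIA females. Of 31 dendrite and axon growth genes 9 rose and 4 fell, and 10 rose and 5 fell when adjusted over the list alone. The list did not pass (adjusted p = 0.386), and its median of -0.02 lay opposite to its mean of 0.05 and its upward test. Dpysl2 rose by 0.41 (SE 0.07, adjusted p = 0.000386), Marcks by 0.40 (SE 0.07, adjusted p = 0.000506) and Sema5a by 0.52 (SE 0.10, adjusted p = 8e-04). In neurotrophin and CREB signalling 5 of 25 rose and 1 fell (camera adjusted p = 0.0954, fry adjusted p = 0.00297), and Creb1 rose by 0.50 (SE 0.08, adjusted p = 0.00029), or by 0.23 (adjusted p = 0.0302) after removal of the GC and length trend. Bdnf rose from 51 ± 4.04 to 67.9 ± 6.82 CPM (SD, n = 4 each), a log2 change of 0.41 (SE 0.11, adjusted p = 0.0116). Bdnf lost its call without sPIA female 3 (0.35, adjusted p = 0.0538) and after removal of the GC and length trend (0.22, adjusted p = 0.288). Immediate early genes included 3 risen and 5 fallen of 28, and 3 risen and 7 fallen when adjusted over the list alone (adjusted p = 0.0996). Nr4a2 fell by 0.90 (SE 0.18, adjusted p = 0.00276).

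Some glial, stress and immune genes passed singly in sPIA females. Of 22 astrocyte markers 4 rose and 1 fell (adjusted p = 0.742), and Sox9, a transcription factor of astrocytes and progenitors, rose by 0.76 (SE 0.13, adjusted p = 0.000262). Of 27 unfolded protein and integrated stress response genes 6 rose, and 7 when adjusted over the list alone (adjusted p = 0.0996), among them the chaperone Hsp90b1 (0.42, SE 0.08, adjusted p = 0.000683). Il1a, which encodes interleukin 1 alpha, rose from 0.0743 ± 0.0577 to 0.71 ± 0.0883 CPM (SD, n = 4 each, adjusted p = 0.0119), a low level at which few counts were read. Choroid plexus and ependymal markers did not pass (0 of 21 called; median 0.09, adjusted p = 0.742).

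Heme synthesis and iron genes included 2 known responders to anemia in sPIA females. Alas2, the erythroid enzyme that starts heme synthesis, rose from 3.39 ± 0.764 to 10.5 ± 6.62 CPM (SD, n = 4 each), a log2 change of 1.63 (SE 0.48, adjusted p = 0.0276). Tfrc rose from 249 ± 42.1 to 432 ± 133 CPM (SD, n = 4 each), a log2 change of 0.79 (SE 0.25, adjusted p = 0.037). As lists, heme synthesis (2 risen of 11, adjusted p = 0.656; median -0.12 against a mean of 0.04 and a downward test) and iron homeostasis (1 risen and 1 fallen of 25, adjusted p = 0.661) did not pass. Slc2a1 did not pass (0.11, SE 0.12, adjusted p = 0.626). Alas2 lost its call without NBC female 1 (0.0605), NBC female 2 (0.0796), NBC female 4 (0.0625) or sPIA female 2 (1.15; 0.103), and with limma-voom (0.115). Tfrc lost its call without NBC females 1, 2 or 3 (0.0963, 0.0899, 0.0787) or sPIA females 3 or 4 (0.139, 0.0791). It was also lost after removal of the GC and length trend (0.53, adjusted p = 0.235).

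The count for sPIA against NBC in females fell to 1421 without NBC female 1 and to 1562 without sPIA female 3, and DESeq2 called 2870 genes and limma-voom 2363. The changes followed GC content across genes (rho -0.48), and removal of each library's GC and length trend, an alternative added after the data had been seen, reduced limma calls from 2436 to 943. Of these 943, 726 were among the 2436, all in the same direction. Between sPIA females and NBC males, which shared P codes but differed in sex and S number, 14 genes passed. Of these, 7 were outside the Y-linked and X-inactivation lists. Over these groups Sst differed by -0.77 (SE 0.14, adjusted p = 0.0216) and Nrn1 by 0.38 (SE 0.07, adjusted p = 0.0202). Adm (0.92), Vegfa (0.37), Kdr (0.36), Fezf2 (-0.51) and Nxph3 (-2.08) did not pass there (adjusted p 0.138, 0.138, 0.134, 0.185 and 0.222). Sox9, which rose in sPIA against NBC females, was at 0.04 (SE 0.13, adjusted p = 0.961).

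Between sPIA and NBC males, both of the P series but apart in S number, 30 genes passed, 13 higher and 17 lower in sPIA. Tmem100, an endothelial transmembrane protein of the BMP pathway (chromosome 11, 90030348 to 90036508, plus strand), rose from 16.3 ± 0.352 CPM (SD, n = 3) to 29.3 ± 2.6 CPM (SD, n = 4), a log2 change of 0.85 (SE 0.12, adjusted p = 0.0017, edgeR). Cxcl12 rose from 76.5 ± 14 (SD, n = 3) to 130 ± 15.6 CPM (SD, n = 4), a log2 change of 0.76 (SE 0.13, adjusted p = 0.0111), and Kdr from 49.8 ± 2.02 (SD, n = 3) to 68.2 ± 7.01 CPM (SD, n = 4), a log2 change of 0.45 (SE 0.09, adjusted p = 0.0194). Cd82, a tetraspanin (chromosome 2, 93419111 to 93463140, minus strand), fell from 10.5 ± 1.69 (SD, n = 3) to 5.04 ± 0.402 CPM (SD, n = 4), a log2 change of -1.06 (SE 0.18, adjusted p = 0.0102). Cryab, a small heat shock protein of glia, fell by 1.33 (SE 0.23, adjusted p = 0.0167) and Cox18, an assembly factor of cytochrome c oxidase, by 0.86 (SE 0.15, adjusted p = 0.0111). Eno1b rose by 3.58 (SE 0.56, adjusted p = 0.0111), but it is a near-identical copy of Eno1 and its reads may be split between them, so its value is uncertain. Adm (0.62, SE 0.24), Vegfa (0.40, SE 0.1), Bdnf (0.15), Tfrc (0.26) and Slc2a1 (-0.20) did not pass. Their adjusted p was 0.284, 0.081, 0.653, 0.747 and 0.585.

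In sPIA males 7 lists passed camera, all downward, and none passed with an estimated correlation or the rotation test fry. Astrocyte markers were lower in 20 of 22 members (median -0.12, adjusted p = 5.26e-05, and adjusted p = 0.662 with an estimated correlation). Glucocorticoid response genes were lower in 22 of 23 (median -0.17, adjusted p = 0.000518, and adjusted p = 0.508 with an estimated correlation), of which 2 fell when adjusted over the list alone. Inhibitory interneurons were lower in 21 of 24 (adjusted p = 0.0329, and adjusted p = 0.718 with an estimated correlation), oligodendrocyte precursors in 15 of 19 (adjusted p = 0.0365, and adjusted p = 0.793 with an estimated correlation) and iron homeostasis in 18 of 25 (adjusted p = 0.0365, and adjusted p = 0.508 with an estimated correlation). Choroid plexus and ependymal markers (19 of 21 lower; median -2.60, adjusted p = 1.12e-05) and meningeal and fibroblast markers (19 of 20 lower, adjusted p = 0.000518) had adjusted p = 0.72 with an estimated correlation, beside Ttr at 2460 and 4380 CPM in NBC males 3 and 4. No member of these lists passed over all genes. Hypoxia and HIF targets (adjusted p = 0.114) and angiogenesis signalling (1 of 25 risen, adjusted p = 0.126) did not pass. Without NBC male 2 the calls of glucocorticoid response (0.0875), oligodendrocyte precursors (0.169) and inhibitory interneurons (0.167) were lost, and without NBC male 3 those of meninges and fibroblasts (0.606), iron homeostasis (0.136) and inhibitory interneurons (0.331). Iron homeostasis was also lost without NBC male 4 (0.243), sPIA male 3 (0.116) or sPIA male 4 (0.0665), inhibitory interneurons without sPIA male 1 (0.0665) or sPIA male 3 (0.0798), oligodendrocyte precursors without sPIA male 3 (0.116) or sPIA male 4 (0.275), and meninges and fibroblasts without sPIA male 3 (0.116).

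Tmem100 passed in all 7 fits of sPIA against NBC in males that left out a mouse. Without NBC male 4 the adjusted p was 0.0911 for Cxcl12, 0.0878 for Kdr, 0.0878 for Cd82, 0.0878 for Cox18, 0.124 for Cryab and 0.0911 for Eno1b. Kdr was also lost without sPIA male 2 (0.0697) or sPIA male 4 (0.057), and Cryab without sPIA male 4 (0.0595). The count was 249 without NBC male 2, 53 without NBC male 3, 4 without NBC male 4, 48 without sPIA male 1 and 18 without sPIA male 4. DESeq2 called 155 genes and limma-voom 22, and 1880 genes had an unadjusted p under 0.05. With only these groups fitted, 6 genes passed. With the library code prefix as a block, 36 genes passed, 4 of them among the 30, and the log2 changes were 0.54 for Tmem100 (adjusted p = 0.154), 0.49 for Kdr (adjusted p = 0.0766) and 0.64 for Cxcl12 (adjusted p = 0.0304).

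Severe was compared with moderate anemia in females to ask what depth of anemia added, and 2499 genes passed (16.1%), 1341 higher and 1158 lower in sPIA. Nxph3 was lower by a log2 change of -3.36 (SE 0.59, adjusted p = 0.00101), Nts by -3.07 (SE 0.59, adjusted p = 0.00178) and Cplx3 by -2.53 (adjusted p = 0.00117). Kdr was higher by 0.30 (SE 0.08, adjusted p = 0.0106) and Bdnf by 0.51 (SE 0.11, adjusted p = 0.00205), though Bdnf did not pass after removal of the GC and length trend (0.31, adjusted p = 0.0924). Adm (0.37, SE 0.21), Vegfa (0.15, SE 0.09), Tfrc (0.41, SE 0.25) and Slc2a1 (-0.22) did not pass (adjusted p 0.254, 0.269, 0.292 and 0.232). The rises included Aldoart1 (1.32, SE 0.22, adjusted p = 0.000168) and Rpl23a (1.19, adjusted p = 4.98e-05), both of which have near-identical copies and are uncertain. Non-bled males, with P codes, averaged 5.31 and 13.3 CPM for these genes, against 5.46 and 13.3 CPM in sPIA females. Zxda, annotated as an unprocessed pseudogene and also uncertain, was higher by 1.19 (adjusted p = 0.000305).

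Oxidative phosphorylation was lower in sPIA than in mPIA females, with 11 of 39 members fallen over all genes and 13 adjusted over the list alone (median -0.13, camera adjusted p = 6.15e-05). A further 5 lists passed camera in this comparison. Immediate early genes (median -0.22, adjusted p = 0.025), glucocorticoid response genes (median -0.23, adjusted p = 0.0472), inhibitory interneurons (median -0.13, adjusted p = 0.0472) and cytosolic ribosomal proteins (median -0.10, adjusted p = 0.025) were lower, and synapse and postsynaptic density genes were higher (median 0.12, adjusted p = 0.0472). With an estimated correlation all 6 had adjusted p = 0.872. Glucocorticoid response genes included 1 risen and 4 fallen of 23, and 1 risen and 6 fallen when adjusted over the list alone. Without mPIA female 3 the calls of immediate early genes (0.114), glucocorticoid response (0.0849), synapse and postsynaptic density (0.0849) and cytosolic ribosomal proteins (0.0849) were lost. Glucocorticoid response was also lost without mPIA female 2 (0.078) or sPIA female 4 (0.0755), synapse and postsynaptic density without sPIA female 1 (0.0863) or sPIA female 4 (0.0842), and cytosolic ribosomal proteins without mPIA female 1 (0.0524) or sPIA female 4 (0.0755). Inhibitory interneurons were lost without mPIA females 2 or 4 (0.0635, 0.0848) or sPIA females 1 or 4 (0.0863, 0.0842). After removal of the GC and length trend the median of cytosolic ribosomal proteins was -0.01. The count for sPIA against mPIA in females was 1582 without mPIA female 1, and limma calls went from 2409 to 1076 with removal of the GC and length trend.

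In males, severe and moderate anemia differed in 762 genes (4.92%), 329 higher and 433 lower in sPIA. Slc2a5, a fructose transporter of microglia (chromosome 4, 150119283 to 150144169, plus strand), was lower at 0.936 ± 0.089 against 4.7 ± 1.33 CPM (SD, n = 4 each), a log2 change of -2.32 (SE 0.34, adjusted p = 0.000364). Slc2a5 lay at 4.19, 1.4, 4.43 and 1.4 CPM in sPIA females 1 to 4 and Eno1b at 5.09, 24, 4.85 and 27.8 CPM. Sources besides anemia were thus not excluded. Nr4a1 was lower by -1.08 (SE 0.14, adjusted p = 0.000269), Egr4 by -0.81 (SE 0.12, adjusted p = 0.000318) and Arc, a synaptic activity gene, by -0.95 (SE 0.17, adjusted p = 0.00602), at 67.7 ± 11.2 against 131 ± 10.2 CPM (SD, n = 4 each). In NBC males Arc lay at 92.7 ± 34.4 CPM (SD, n = 3). Kdr was higher by 0.41 (SE 0.08, adjusted p = 0.00583) and Cxcl12 by 0.43 (SE 0.12, adjusted p = 0.0402). Cxcl12 lost its call without mPIA male 3 (0.0982), mPIA male 4 (0.11), sPIA male 2 (0.121) or sPIA male 3 (0.0579) and after removal of the GC and length trend (0.0796). Adm (-0.07), Vegfa (0.11), Tfrc (-0.07), Bdnf (0.00) and Slc2a1 (-0.28) did not pass, with adjusted p of 0.893, 0.466, 0.894, 0.992 and 0.175. Nr4a1, Egr4, Arc, Kdr and Cxcl12 were named here after their values had been seen.

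Immediate early genes were lower in sPIA than in mPIA males, with 9 of 28 fallen over all genes and 11 adjusted over the list alone (median -0.37, camera adjusted p = 4.32e-09, and adjusted p = 0.334 with an estimated correlation). Glucocorticoid response genes had 7 of 23 fallen and 11 adjusted over the list alone (median -0.30, adjusted p = 6.94e-07, and adjusted p = 0.187 with an estimated correlation). Neurogenesis and cell proliferation genes had 6 of 30 risen and 12 adjusted over the list alone (median 0.31, adjusted p = 5.32e-06, and adjusted p = 0.534 with an estimated correlation), and these 3 lists also passed the rotation test fry. Excitatory hippocampal neurons were lower (median -0.13, adjusted p = 0.00427, and adjusted p = 0.579 with an estimated correlation). These 4 calls held in every fit that left out a mouse. The other 6 lists that passed camera each lost the call when at least 1 mouse was left out and had adjusted p of 0.768 to 0.866 with an estimated correlation. Cholesterol synthesis was higher (adjusted p = 0.00427) and was lost without mPIA male 2 (0.0532), and meninges and fibroblasts were higher (adjusted p = 0.00427) and were lost without mPIA male 2 (0.123) or sPIA male 1 (0.102). The list of choroid plexus and ependyma was higher (adjusted p = 0.0342). It was lost without mPIA males 1, 2 or 4 (0.0511, 0.0896, 0.0686) or sPIA males 1, 2 or 3 (0.0921, 0.063, 0.0703). That of oxidative phosphorylation was lower (adjusted p = 0.0143). It was lost without mPIA male 2 (0.0896) or sPIA males 1, 2 or 3 (0.077, 0.102, 0.0847). Genes of synapse and postsynaptic density were lower (adjusted p = 0.0294) and were lost without mPIA male 2 (0.269), sPIA male 2 (0.0822) or sPIA male 3 (0.0703). Those of glycolysis were lower (adjusted p = 0.0357). They were lost without mPIA males 2 or 3 (0.123, 0.0522) or sPIA males 1, 2 or 3 (0.12, 0.134, 0.0703). The count was 230 without mPIA male 1, 355 without mPIA male 4, 302 without sPIA male 1, 306 without sPIA male 2 and 1340 without sPIA male 4. DESeq2 called 1220 genes and limma-voom 775, and limma calls went from 758 to 189 with removal of the GC and length trend, which followed the changes at rho -0.43.

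Whether anemia acted differently in females and males was tested directly as the difference between the sexes in the anemia effect. For moderate anemia edgeR called 0 genes, DESeq2 0 and limma-voom 0, while 1103 genes had an unadjusted p under 0.05 and 69 passed without NBC male 2. The difference was 0.71 for Adm (SE 0.33, adjusted p = 0.688). For Vegfa (0.07), Bdnf (-0.25), Tfrc (0.05) and Slc2a1 (0.25) adjusted p was 0.939, 0.773, 0.985 and 0.805. Camera called 18 lists here, 15 with a more positive change in females, none of which passed with an estimated correlation (adjusted p of at least 0.392) or the rotation test fry. Meningeal and fibroblast markers had a median difference of 1.18 (adjusted p = 2.37e-11), and choroid plexus and ependymal markers had a median difference of 2.33 (adjusted p = 1.09e-07), beside Ttr at 2460 and 4380 CPM in NBC males 3 and 4.

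For severe anemia 147 genes passed the test of the difference between the sexes, 93 with a more positive change in females and 54 with a more negative one. Cd82 differed by 1.23 (SE 0.25, adjusted p = 0.0224), Prss12, the neurotrypsin gene, by -1.25 (SE 0.25, adjusted p = 0.0224) and Ctsc, a lysosomal protease, by 1.19 (SE 0.27, adjusted p = 0.0315). Aldoart1 differed by 1.64 (SE 0.32, adjusted p = 0.0196) and Eno1b by -3.27 (SE 0.71, adjusted p = 0.0391), both uncertain because of near-identical copies. The effect on Adm differed by 1.15 (SE 0.33, adjusted p = 0.0841). For Kdr (0.12), Cxcl12 (-0.02), Vegfa (0.11), Bdnf (0.26), Tfrc (0.54) and Slc2a1 (0.31) adjusted p was 0.666, 0.97, 0.726, 0.433, 0.489 and 0.415. No sex difference was called for these genes. Without sPIA female 2 the difference in Adm was 1.34 and passed (adjusted p = 0.035). Camera called 9 lists, none with an estimated correlation or fry. Cytosolic ribosomal proteins and oxidative phosphorylation changed more negatively in females (adjusted p = 0.00155 and 0.00226), and astrocytes and unfolded protein response genes more positively (adjusted p = 0.00173 and 0.00384), with adjusted p of 0.651 to 0.696 with an estimated correlation. The count was 5 without NBC female 1, 17 without sPIA male 4, 42 without sPIA female 3, 49 without NBC male 4, 79 without NBC female 3, 312 without sPIA male 1 and 327 without NBC male 2. Aldoart1 lost its call without NBC female 1 (0.0507), and Cd82 without NBC male 4 (0.0504), NBC female 1 (0.0555) or sPIA male 4 (0.0528). Prss12 lost its call without NBC male 4 (0.0637), NBC female 1 (0.068), sPIA male 4 (0.0528) or sPIA female 3 (0.0565), and Ctsc without NBC male 4 (0.085), NBC females 1, 3 and 4 (0.0753, 0.0562 and 0.0504), sPIA male 4 (0.0751) or sPIA female 3 (0.0578). Eno1b lost its call without NBC males 3 or 4, any NBC female, sPIA males 3 or 4 or sPIA female 3, with adjusted p of 0.0511 to 0.0968. Among the lists, oxidative phosphorylation was lost without NBC male 2 (0.355), NBC female 2 (0.0515) or sPIA male 4 (0.071), astrocytes without NBC male 3 (0.0545) or sPIA female 1 (0.107), and the unfolded protein and integrated stress response without NBC male 3 (0.0656). DESeq2 called 463 genes, limma-voom 114 and the fit of only these groups 5, and 2559 had an unadjusted p under 0.05.

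Females and males were also compared in the non-bled controls, and 1570 genes passed (10.1%), 721 higher and 849 lower in females, or 1561 without the Y-linked and X-inactivation lists. Besides Xist (log2 difference 11.87) and the Y-linked genes, Mir6236 was higher in females (1.77, SE 0.35, adjusted p = 0.00597) at 81.1 ± 16.8 (SD, n = 4) against 23.7 ± 6.35 CPM (SD, n = 3). Bdnf (-0.15), Slc2a1 (-0.10), Tfrc (-0.10) and Vegfa (-0.13) did not pass (adjusted p 0.441, 0.67, 0.846 and 0.414). Adm, named after its value was seen, was lower in females (-0.85, SE 0.26, adjusted p = 0.0349). The Adm call was lost without NBC male 2 (0.081), NBC male 4 (0.0777) or NBC females 1, 2 and 3 (0.059, 0.0799 and 0.083). Cytosolic ribosomal proteins were higher in females, with 12 of 38 called and 14 adjusted over the list alone (camera adjusted p = 0.000114, and adjusted p = 0.656 with an estimated correlation), as was oxidative phosphorylation with 7 of 39 called and 11 adjusted over the list alone (adjusted p = 0.000144, and adjusted p = 0.728 with an estimated correlation). After removal of the GC and length trend both lists had adjusted p = 0.773, and oxidative phosphorylation was lost without NBC male 2 (0.202). Astrocyte markers were lower in females, with 4 of 22 called (adjusted p = 0.00401, and adjusted p = 0.728 with an estimated correlation), and this call was lost without NBC male 3 (0.15). The count was 440 without NBC male 4 and 589 without NBC female 1, and the NBC females carried numbered codes and the NBC males P codes, so sex and code series could not be told apart. In comparisons added after these counts had been seen, females and males differed in 387 genes within mPIA and in 8 within sPIA, where both sexes carried P codes. Of those 8, 7 lie on the sex chromosomes and 1 is Fbxo44.

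Called genes were then compared between anemia levels and sexes. In mPIA no gene was called in both sexes. In sPIA 6 genes were higher and 3 lower in both sexes, among them Kdr, Cxcl12, Tmem100 and Dgke, and 1 went in opposite directions. Independent lists would give 1.06 and 1.34. Dgke (chromosome 11, from 89035179) lies near Tmem100, so they are not independent and these overlaps decide nothing. In females Adm was called at both anemia levels (0.0812 expected), and in males 4 genes were lower at both, namely Cd82, Adamts1, Spon2 and Ppfibp2 (0.0846 expected). The anemia levels of a sex share their controls, and in 20 simulations of unchanged groups the overlap was at most 0. Across genes, which are not independent replicates, r of the 2 anemia effects was 0.22 in females (0.52 simulated), and the covariance 0.015 (0.0325 simulated). With the NBC females split into separate controls, r was -0.19 to 0.03 over 6 splits. In males r was 0.64 (0.57 simulated) and the covariance 0.131 (0.0408 simulated), and 3 controls could not be divided into pairs. NBC spread was 8.66% in females and 20.7% in males, which the simulated covariances do not follow. The simulations thus decide nothing, and shared controls may give part of the excess.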

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

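The test of the choroid plexus covariate on the 77 lower genes in mPIA males was chosen only after its result was seen. That covariate, the removal of GC and length trends and the comparisons of the sexes within mPIA and sPIA were added after seeing the data. Single libraries far from the others of their group were sought with Dixon's criterion in 45 groups of 4 values, and 5 lay beyond its 95% critical value, where chance gives about 1 in 20 groups. These were the total of mPIA female 3, at 44.4 mega-counts against 16.5 to 20 in the others, and Tfrc in NBC female 4, at 312 CPM against 222 to 232 CPM. Sst in mPIA male 3 lay at 113 CPM against 158 to 162 CPM. Ttr lay at 2020 CPM in NBC female 2 against 21.7 to 43 CPM, and at 1320 CPM in sPIA female 2 against 2.29 to 106 CPM.

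In a direct test of the difference between the sexes in the effect of severe anemia 147 genes passed, and only the female arm crosses code series. Other splits also reached this count (5 of 60, the real one included) but decide nothing, as some kept all NBC females together. Named genes with a more negative effect in females were Sst (difference -0.82, with -1.22 in females and -0.41 in males, adjusted p = 0.0463), Fezf2 (-0.94, with -1.03 and -0.09, adjusted p = 0.0271), Stx1a (-0.51, adjusted p = 0.0271), Prss12 (-1.25, adjusted p = 0.0224), Eno1b (-3.27, adjusted p = 0.0391), Col24a1 (-3.22, adjusted p = 0.0469), Prph (-2.39, adjusted p = 0.0477) and Adamts16 (-1.6, adjusted p = 0.0484). Those with a more positive effect in females were Sox9 (difference 0.88, with 0.76 in females and -0.12 in males, adjusted p = 0.0231), Creb1 (0.49, adjusted p = 0.0488), Hsp90b1 (0.46, adjusted p = 0.0477), Pdia4 (0.57, adjusted p = 0.0341), Sema5a (0.57, adjusted p = 0.0477), Irs1 (0.44, adjusted p = 0.0484), Aldoart1 (1.64, adjusted p = 0.0196), Cd82 (1.23, with 0.17 in females and -1.06 in males, adjusted p = 0.0224), Ctsc (1.19, adjusted p = 0.0315), Trpm3 (1.27, adjusted p = 0.0477) and Ecm2 (1.47, adjusted p = 0.0477). With a mouse left out the count was 5 (NBC female 1) to 327 (NBC male 2).

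The count of 2472 genes between sPIA and NBC females is the largest against controls, and it stands on a change of library code series and S numbers. Removal of each library's GC and length trend took the limma calls to a ratio of 0.39 (2436 before, 943 after, 726 shared). Over the 1710 lost calls the median change went from 0.32 (SE 0.09) to 0.15 (SE 0.08). A GC or length bias is thus a candidate source of part of the count. Of the 109 called genes that the naming rule took 63 still passed, Adm, Kdr, Sst and Fezf2 among them. By design a difference between code series could not be told apart from anemia. Of 1561 genes called between NBC females and NBC males outside the sex-linked lists, 98.7% moved toward the male level in sPIA against mPIA females. The median move was 0.3, beside a median NBC difference of 0.37. Over these genes the female and male levels in sPIA, both with P codes, differed by a median of 0.03. These values go with a code series difference as a source of part of the count, and anemia was not excluded. Over the same genes mPIA males (M codes) differed from mPIA females (numbered codes) in the called direction for 92%, with a median of 0.17 against 0.35, a ratio of 0.5 that sex differences may also give. Severe anemia stays open as a cause. Its effect in males over the 2472, within the P series but across S numbers, had the same sign for 71.2% (median ratio 0.19). This lies between a shared effect and none.

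In mPIA males the 77 lower genes and the 24 higher genes parted in their tests. Over the 77 lower genes the choroid score as a covariate reduced the median fold to a ratio of 0.45 (-1.69, SE 0.34, to -0.75, SE 0.34), so choroid plexus and ependymal tissue in NBC males 3 and 4 is a candidate source of these falls, and a ratio of 0.66 without NBC male 4 (-1.12, SE 0.32) left open how far that mouse alone accounts for them. Over the 24 higher genes, which include Bhlhe40 and Nr4a1, the ratio without NBC male 4 was 0.94 (0.5 against 0.53, SE 0.13). They were chosen by calls that used this mouse, and 0 passed without it. The ratio is thus weak evidence against it alone as the source. A choroid plexus share stayed open for these genes (ratio 0.79; 0.42, SE 0.14, against 0.53, SE 0.12). Moderate anemia was not separated from the M code series and may contribute.

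In mPIA females, within a single code series, the hypoxia and endothelial lists were higher than other genes by camera, and fry passed for hypoxia alone (adjusted p = 0.0181 against 0.656). For the hypoxia list the tables argue against a larger share of vascular cells, since its 30 members outside the vascular lists still passed with the endothelial mean as a covariate (camera p = 1.06e-05, and p = 0.000554 with an estimated correlation), with Adm at 1.49 (SE 0.26), and for both lists against a GC or length bias (camera p = 3.03e-13 and 2.79e-14 after its removal). They also argue against the deeper library, mPIA female 3, as the source (adjusted p = 5.55e-11 without it for hypoxia and 4e-10 for endothelial markers). For the endothelial list a larger share of vascular cells remained a candidate explanation, as the log2 changes of its 24 members, 20 of them positive, differed from a common mean of 0.13 by no more than their errors (chi-square 28.1 on 23 degrees of freedom, p = 0.213). A response to low oxygen in moderate anemia is a hypothesis for the hypoxia list, and no separate measure of it was tested.

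Other divisions of the same mice were used to ask how often chance gives as many calls. In females only the real split of 35 gave as many calls for sPIA against NBC (2472, highest other 92) and mPIA (2499, highest other 483). The same held for sPIA against mPIA in males (762, 5) and females against males in NBC (1570, 174). This speaks against chance alone, but each comparison crosses code series, which splits cannot tell from anemia or sex. Chance was not excluded for mPIA (2 of 35; 101 against 328) or sPIA (6 of 35; 30 against 352) against NBC in males. The sex difference of the sPIA effect (5 of 60 drawn; 147 against 832) was not decided. Splits with 832, 699 and 233 calls kept the NBC mice of 1 sex together, as the real one does. That with 150 mixed them. For the sex difference of the mPIA effect the real count of 0 makes every split as large (60 of 60; highest other 309), so nothing is decided. For mPIA against NBC in females 1 of 35 splits gave as many as the real 1 call (highest other 0). This sets a single call against 0 and mixes mice of different code prefixes, so it is weak evidence against chance. The count rests on Adm, whose call was lost in 7 of 8 fits without a mouse and with the code prefix as a block (adjusted p = 0.156). Why some splits of the males called more genes was not tested. That with 328 calls put NBC males 3 and 4 with mPIA male 2.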

How the results depend on the processing

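All alternatives but the choroid covariate and the removal of GC and length trends, and the gene lists, were fixed before the data were examined. Over all alternatives, named genes kept direction and side of the threshold in 4009 refits, lost the threshold in 665, gained it in 8 and turned direction in 39. Lists did so in 906, 364, 0 and 3. RLE or upper quartile scaling, either low-count filter, and leaving out haemoglobin and mitochondrial genes kept every count of genes within 1.5 times. The cause was not tested except where stated. Depth limited genes near the filter, such as Il1a.

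Counts with the GC and length trend removed are by limma, and the limma count before removal follows "from". For mPIA against NBC in females, whose main count was 1 gene, other settings gave 0 (code prefix as a block, limma-voom) and 2 (only the groups compared; quality weights), and leaving out a mouse gave 0 to 1. For mPIA against NBC in males 101 became 0 (choroid covariate), 0 (only the groups compared), 24 (limma-voom), 29 (quality weights) and 381 (DESeq2), and 0 to 1124 with a mouse left out. For sPIA against NBC in females 2472 became 943 (GC and length trend removed, from 2436) and 1421 to 2705. For sPIA against NBC in males 30 became 13 (choroid covariate), 6 (only the groups compared), 1 (quality weights), 155 (DESeq2) and 4 to 249. For sPIA against mPIA in females 2499 became 4505 (quality weights), 1076 (GC and length trend, from 2409) and 1582 to 2769. For sPIA against mPIA in males 762 became 307 (only the groups compared), 390 (quality weights), 1220 (DESeq2), 189 (GC and length trend, from 758) and 230 to 1340. The sex difference of the mPIA effect had 0 to 69 genes with a mouse left out, its main count being 0. The sex difference of the sPIA effect went from 147 to 34 (choroid covariate), 5 (only the groups compared), 15 (quality weights), 463 (DESeq2), 33 (GC and length trend, from 128) and 5 to 327. For female against male in NBC 1570 became 744 (choroid covariate), 668 (only the groups compared), 844 (quality weights), 348 (GC and length trend, from 1526) and 440 to 2152.

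Counts of lists that passed camera fell with an estimated correlation from 12 to 3 (mPIA females), from 11, 5, 7, 6, 10, 18 and 9 to 0 (mPIA males, sPIA females, sPIA males, sPIA against mPIA in females and in males, and the sex differences for mPIA and sPIA) and from 8 to 2 (females against males in NBC). With fry they were 1 for mPIA females, 0 for mPIA males, sPIA males and both sex differences, 3 for sPIA against mPIA in each sex and 5 for females against males. With the choroid covariate they were 7 for mPIA males, 4 for sPIA males, 3 for the sex difference for sPIA and 5 for females against males, and with the GC and length trend removed 11 for sPIA females and 11 for sPIA against mPIA in females. With a mouse left out they were 6 to 17 and 7 to 15 for mPIA females and males, 5 to 11 and 3 to 9 for sPIA females and males, 2 to 8 and 4 to 14 for sPIA against mPIA in females and males, 11 to 19 and 3 to 13 for the sex differences for mPIA and sPIA, and 5 to 10 for females against males.

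Values that turned direction were mostly close to 0. Bdnf in sPIA against mPIA males turned to 0.01 with RLE, upper quartile, the stricter filter and DESeq2, 0.00 with haemoglobin genes left out or only these groups, 0.02 with the choroid covariate and 0.06 with quality weights, and spanned -0.1 to 0.07 with a mouse left out. Bdnf also turned to -0.01 with the code prefix as a block in sPIA males and to 0.04 with the GC trend removed in females against males. With a mouse left out Bdnf spanned -0.01 to 0.24 in mPIA males and 0.00 to 0.25 in sPIA males. Slc2a1 turned to -0.02 with the choroid covariate in mPIA males, and spanned -0.04 to 0.27 there and -0.22 to 0.09 in females against males. Tfrc spanned -0.24 to 0.08 in sPIA against mPIA males. It spanned -0.21 to 0.19 in the sex difference for mPIA, where it turned to -0.03 with quality weights or the GC trend removed. In females against males it spanned -0.24 to 0.16 and turned to 0.02 and 0.15 with the same settings. Vegfa spanned 0.00 to 0.17 in the sex difference for mPIA, and Gria2 turned to -0.07 with the GC trend removed in sPIA females. Adm turned to 0.04 with the choroid covariate in sPIA against mPIA males, and Cxcl12 in the sex difference for sPIA turned to 0.01 with quality weights and spanned -0.16 to 0.12. Without a mouse the medians spanned -1.69 to 0.11 for choroid markers and -0.02 to 0.09 for immediate early genes in mPIA females, and the ribosomal median in sPIA against mPIA females stayed at -0.01 with the test turned when the GC trend was removed.

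Replicate numbers did not pair the mice by the rule of a correlation over 0.1 in every pair. The correlations of deviations between equal numbers spanned 0.04 to 0.15 in mPIA against NBC females, where 3 of 4 pairs exceeded 0.1 and all 8 libraries correlated best with their own number, a hint from the data. The labels give equal numbers the same code prefix there (86, 86, 90 and 91) without its meaning, and with the replicate number as a block Adm had adjusted p = 0.144. They spanned -0.06 to 0.01 in mPIA males, -0.01 to 0.09 in sPIA females and -0.08 to -0.05 in sPIA males. With the replicate number as a block the counts of genes were 0, 74, 2312 and 26 for mPIA females, mPIA males, sPIA females and sPIA males, 2365 and 632 for sPIA against mPIA in females and males, and 0 and 107 for the sex differences. With this block 11 lists passed in sPIA males, and Tfrc turned to -0.05 in the sex difference for mPIA. The block could not be estimated for females against males in NBC, and the code prefix block only for mPIA females and sPIA males.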

Other observations

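Of 31 mTOR and insulin signalling genes in sPIA females 4 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.806).

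Nxph3 and Nts also varied within the male groups. Nxph3 lay at 4.79 to 20 CPM in NBC males and 2.38 to 23.2 CPM in sPIA males. In females these were 9.71 to 34.4 and 1.86 to 4.88 CPM. In all, mPIA males differed from NBC females in 288 genes and sPIA males from NBC females in 3238. Genes annotated as pseudogenes, which can collect reads of their parent genes, were called in 9.68% of 93 tested in sPIA females, against 16% of other genes (Fisher's exact test p = 0.117).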
